A study of Mus musculus with 22 samples.

How the data were processed

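Messenger RNA was measured by RNA sequencing in 22 libraries of spinal cord from mice aged 7 months. The genotypes were wild type (WT, 6 libraries), heterozygous for the E196K change in the tyrosyl-tRNA synthetase gene Yars (HET, 6 libraries) or homozygous for it (HOM, 10 libraries), on a mixed B6N and B6J background. Each library was placed in its group by the genotype given in the labels, and the replicate numbers used here follow the order of deposition and pair nothing. The labels do not say in words that every library came from a separate mouse, so the p-values measure the spread between these libraries. Total RNA was purified with TRIzol and miRNeasy columns with a DNase step, and libraries were made from polyA-selected RNA with stranded KAPA kits and sequenced as paired ends, per the labels' protocols.

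The authors deposited, for each library, the gene table written by RSEM, which holds expected counts, TPM and FPKM per Ensembl gene, per the file headers. The submitters' processing notes name Bowtie2 2.2.0 and RSEM 1.2.12; the roles of the tools, the genome build, the annotation release and the strand setting are not given in the sources used here. The deposited expected counts share reads that map to several genes or isoforms among them, so they need not be whole, and between 14.41% and 16.23% of the values per library were not whole numbers. The deposited TPM values, scaled by the authors' RSEM run to transcript length and to a fixed total, were used in an alternative test, and the deposited FPKM values and the lengths were not used. Because reads of near-identical genes are shared by the model in RSEM, and the strand setting is not given, members of close families and genes that overlap a gene on the other strand carry that uncertainty. The files held 38924 gene IDs, and 37607 of them had a GRCm38 position in GENCODE M21, matched by Ensembl ID; symbols came from a table of gene names by the same IDs.

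Expected counts were rounded to whole numbers. The rounded totals ran from 24.45 M to 42.81 M counts per library. Genes were kept by edgeR's filterByExpr with the genotypes as groups, which left 16974 genes. Libraries were scaled by TMM, and all 22 libraries were fitted together with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3. HOM was compared with WT, HET with WT and HOM with HET, and the number of E196K alleles was tested as a numeric term. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes were derived from the F statistic of each test. Levels are given as CPM, counts scaled by the TMM-adjusted total of the tested genes. No count was added for the means, and fitted fold changes of genes with almost no reads in a group depend on the prior count of the fit, so ratios of summed counts with exact 95% binomial intervals are given for those, and a group with no reads was set to a floor of 3 counts over the group. Intervals and floors rest on counts summed over a group, so they cover counting error only and leave out the spread between libraries. The reads also carry no molecular identifiers.

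The 41 gene lists, of 10 to 38 genes each, covered stress and metabolic pathways and the cell types that spinal cord or tissue next to it could hold; 3 list genes had no match in the files. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated for each list. The estimated correlation was applied in the main fit only. List p-values with a covariate, another filter or fewer libraries used the preset correlation. Counts of members that passed the test over all genes and adjusted over the list alone were kept beside each list test. These 41 lists, the planned tests and the rule for naming genes were fixed before the data files were opened. The groups of Hox genes by position along the body axis, the tests on single libraries and the tests of explanations in the closing section were made after results had been seen. The rule named Yars; in HOM against WT the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean of at least 1 CPM; the 8 and 8 in HET against WT and the 5 and 5 in HOM against HET, or the 5 genes with the smallest p where fewer than 5 were called; 4 members with the smallest p of every called list; and 2 members of the lists for ATF4 targets, tRNA synthetases, motor neurons, microglia, astrocytes, axon injury and Schwann cells whether called or not. Clone names, Xist and Y-linked genes were not named under it, and a few genes that it would name are not reported here. Further genes named in the text were chosen after seeing the data.

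Further properties of the libraries were tabulated. Title numbers in the labels begin with 39992, 40411 or 40412, which the labels do not explain, and the genotypes were spread unevenly over them. The labels give no sex, and Xist was used as a numeric covariate in an alternative. Libraries of a group were compared pairwise by a chi-square statistic over genes, which was at least 4.41 per degree of freedom, so no pair agreed within sampling noise.

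Alternatives to these choices were RLE scaling, DESeq2 1.42.0, limma voom, limma-trend on log2(TPM + 1), no filter on low counts, a filter of at least 1 CPM in 6 libraries, the title prefix or the Xist level as a covariate, the libraries of prefixes 40411 and 40412 alone, a fit with only the groups compared, and leaving out each library in turn. A fit without HOM 3 and HET 4 and a fit with the level of Gm42418, an annotated gene at a ribosomal RNA locus, as a covariate were chosen after seeing the data. The fit was tested on simulated data made from the real means, dispersions and library sizes with 50 genes changed at each of 4 sizes. In HOM against WT it called 48% of genes changed by 0.25 on the log2 scale, 78% at 0.5, 96% at 1 and 100% at 2, with 11 of 16738 unchanged genes called. In HET against WT it called 44%, 74%, 84% and 100% at those sizes, with 7 of 16738 unchanged genes called. In the same simulated data 36 genes of the ATF4 list were raised by 0.15 in HOM. The list test with the preset correlation then called 1 list in HOM against WT. In HET against WT, where no list was shifted as a set, it called 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.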

Results

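Yars, the gene that carries the E196K change and encodes the enzyme that charges tyrosine tRNA, was transcribed at a similar level in the 3 genotypes: 113 CPM in WT (SD 3.77, n = 6), 115 CPM in HET (SD 4.38, n = 6) and 121 CPM in HOM (SD 6.02, n = 10). The log2 fold change was 0.10 in HOM against WT (SE 0.0332, adjusted p = 0.643), 0.02 in HET against WT (SE 0.037, adjusted p = 1) and 0.08 in HOM against HET (SE 0.0332, adjusted p = 0.467). Adjusted over the list alone, Yars was among the 9 tRNA synthetase genes that passed in HOM against WT (p = 0.021). A protein change need not alter the level of the transcript, so these values do not test the genotype labels. All p-values here measure only the spread between these libraries, since the labels do not say that each came from a separate animal.

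Homozygous cords differed from wild type cords in 16 genes, 10 of them on the list of targets of ATF4, the transcription factor of the integrated stress response. Fgf21, a secreted metabolic hormone, had no read in any of the 6 WT libraries and 1108 counts in HOM, at least 61 in each of the 10 libraries (3.34 CPM, SD 1.17), which was at least 226-fold higher (adjusted p = 7.75e-08). Cdsn, which encodes the skin adhesion protein corneodesmosin, rose 5.21-fold from 0.407 to 2.14 CPM (SD 0.108 and 0.382, adjusted p = 1.97e-08). Stbd1, which tethers glycogen for breakdown, rose 3.37-fold from 1.25 to 4.22 CPM (SD 0.167 and 1.06, adjusted p = 7.75e-08). Slc7a1, a carrier of cationic amino acids, rose 1.32-fold from 71.2 to 94.1 CPM (SD 3.08 and 6.4, adjusted p = 1.01e-06).

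Further ATF4 targets rose from low levels. Adm2, a secreted peptide of the calcitonin family, had 1 count in WT and 118 in HOM, a ratio of 72.3 (12.7 to 2880, adjusted p = 1.01e-06). B4galnt2, a glycosyltransferase, had 9 counts in WT and 299 in HOM, a ratio of 20.4 (10.6 to 45, adjusted p = 1.25e-06). Gdf15, a secreted stress hormone, had 11 and 121 counts, a ratio of 6.74 (3.64 to 13.9, adjusted p = 0.00245). Intervals and floors cover counting error only. Chac1, which degrades glutathione, rose 1.46-fold from 6.86 to 10 CPM (SD 0.514 and 1.22, adjusted p = 0.000359).

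Among genes at higher levels the rises were small. Atf4 itself rose from 77.3 to 90.6 CPM (log2 fold change 0.23, SE 0.0383, adjusted p = 0.00461), and Cyb5r1, a reductase, from 19.4 to 24.2 CPM (0.32, SE 0.0418, adjusted p = 0.000124). The synthetases for cysteine and tryptophan tRNA rose: Cars by 0.19 (SE 0.0303, adjusted p = 0.00215) and Wars by 0.17 (SE 0.0316, adjusted p = 0.0209). Aldh18a1, of proline synthesis, rose by 0.25 (SE 0.0454, adjusted p = 0.0132), Acsl5, which activates fatty acids, by 0.17 (SE 0.0294, adjusted p = 0.0104), and Sesn2, a sensor of leucine that restrains growth signalling, by 0.28 (SE 0.0545, adjusted p = 0.0285). Mrvi1, which acts in smooth muscle calcium release, was the only gene that fell, from 10.9 to 7.95 CPM (-0.45, SE 0.0842, adjusted p = 0.0185). HOM 3 had the highest Mrvi1 value of its group, 11 CPM.

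**Figure D1:**
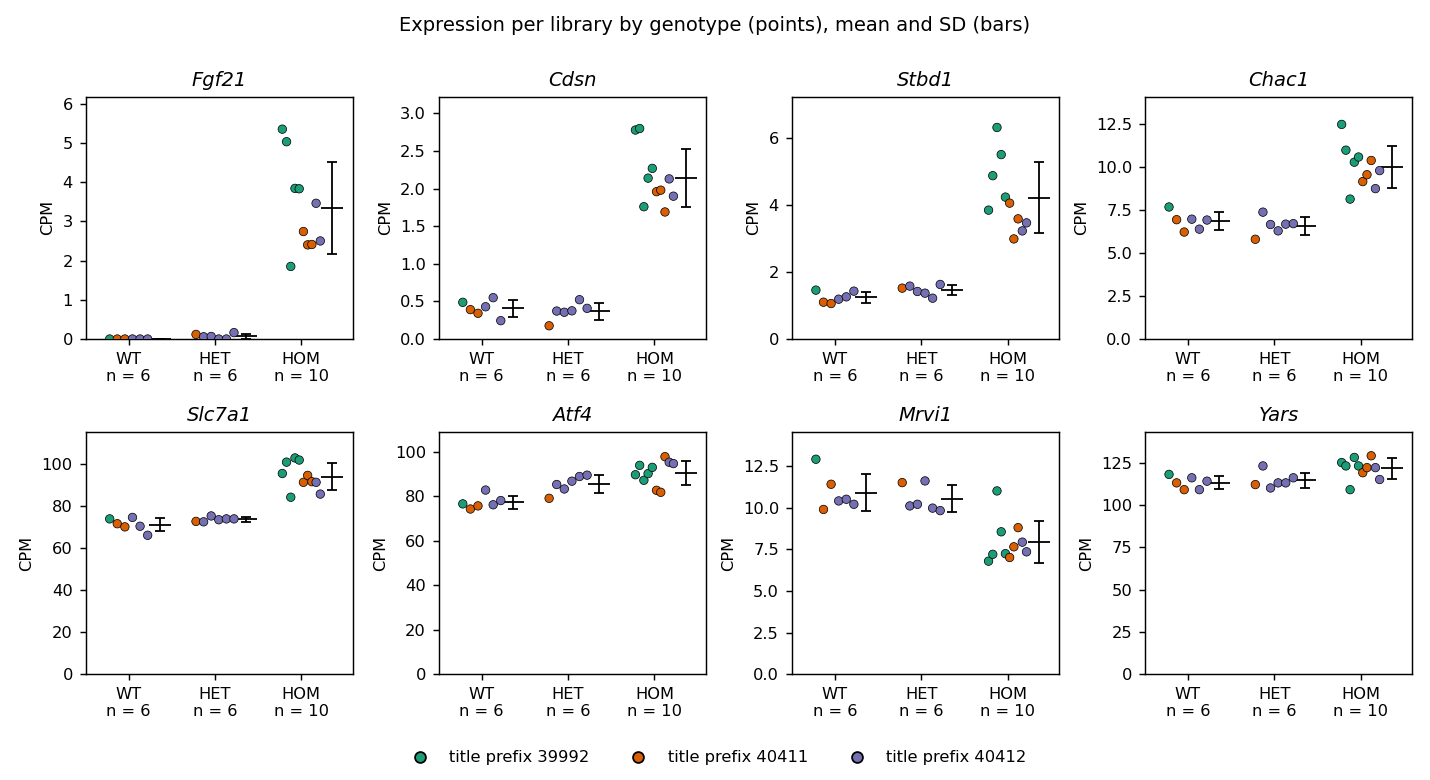
Level of Fgf21, Cdsn, Stbd1, Chac1, Slc7a1, Atf4, Mrvi1 and Yars in each library by genotype, colored by the prefix of the sample title. Bars show the mean and SD of each group.

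The test called 15 genes higher and 1 lower at an adjusted p below 0.05, and 1004 genes had an unadjusted p below 0.05, where 849 were due by chance. All 16 genes differed in the same direction within each of the 3 title prefixes, with Stbd1 log2 differences of 1.70, 1.66 and 1.34. Those prefixes held 5, 3 and 2 HOM libraries and 1, 2 and 3 WT libraries. The genes were chosen in these same libraries, so their shared direction was largely fixed in advance. The weakest calls depended on single libraries: Wars was lost without HOM 1, 4, 5 or 6 or WT 2, 3, 4 or 5 (highest adjusted p = 0.114, without WT 5), and Sesn2 without HOM 1, 4, 5, 6 or 7 or WT 1, 3, 4 or 5 (highest 0.153, without WT 5). Aldh18a1 was lost without WT 1, 3 or 5 (highest 0.0528, without WT 3), Acsl5 without WT 1 or 4 (highest 0.0569, without WT 4), and Mrvi1 without WT 1 or 3 (highest 0.0943, without WT 1). Limma-trend on log2(TPM + 1) called 12 genes, 11 of them shared with the 16. Lost there were Mrvi1 (log2 fold change -0.235, adjusted p = 0.74), Aldh18a1 (adjusted p = 0.444), Acsl5 (0.106), Sesn2 (0.0705) and Wars (0.0585). A fit with only the groups compared called 12, all shared, and lost Sesn2 (adjusted p = 0.149), Wars (0.11), Acsl5 (0.0808) and Mrvi1 (0.079).

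As a list, ATF4 and integrated stress response targets rose in HOM against WT: of 38 measured members 34 were higher, 10 passed over all genes and 22 passed adjusted over the list alone, with none lower (median log2 fold change 0.21, adjusted p = 9.87e-67 and 1.61e-09 with an estimated correlation). The transcript of Atf4 and the serine and one-carbon enzymes Shmt2 (0.21, SE 0.0425) and Mthfd1l (0.21, SE 0.0465) were among the 22, as were the proline enzyme Pycr1 (0.63, SE 0.144) and the leucine carrier Slc7a5 (0.31, SE 0.0744). Of 20 genes of the endoplasmic reticulum unfolded protein response 11 were higher, none passed, and the median was 0.01 (adjusted p = 0.871). The cytosolic tRNA synthetases rose slightly as a list: 20 of 23 were higher, 2 passed and 9 passed adjusted over the list alone (median 0.06, adjusted p = 7.34e-11, but adjusted p = 0.12 with an estimated correlation). Beyond Cars and Wars, the members Aars (0.17, SE 0.0389), Mars (0.15, SE 0.0379) and Rars (0.11, SE 0.0261) were among the 9. Of 17 mitochondrial synthetases 11 were higher and none passed (median 0.03, adjusted p = 0.658).

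**Figure D2:**
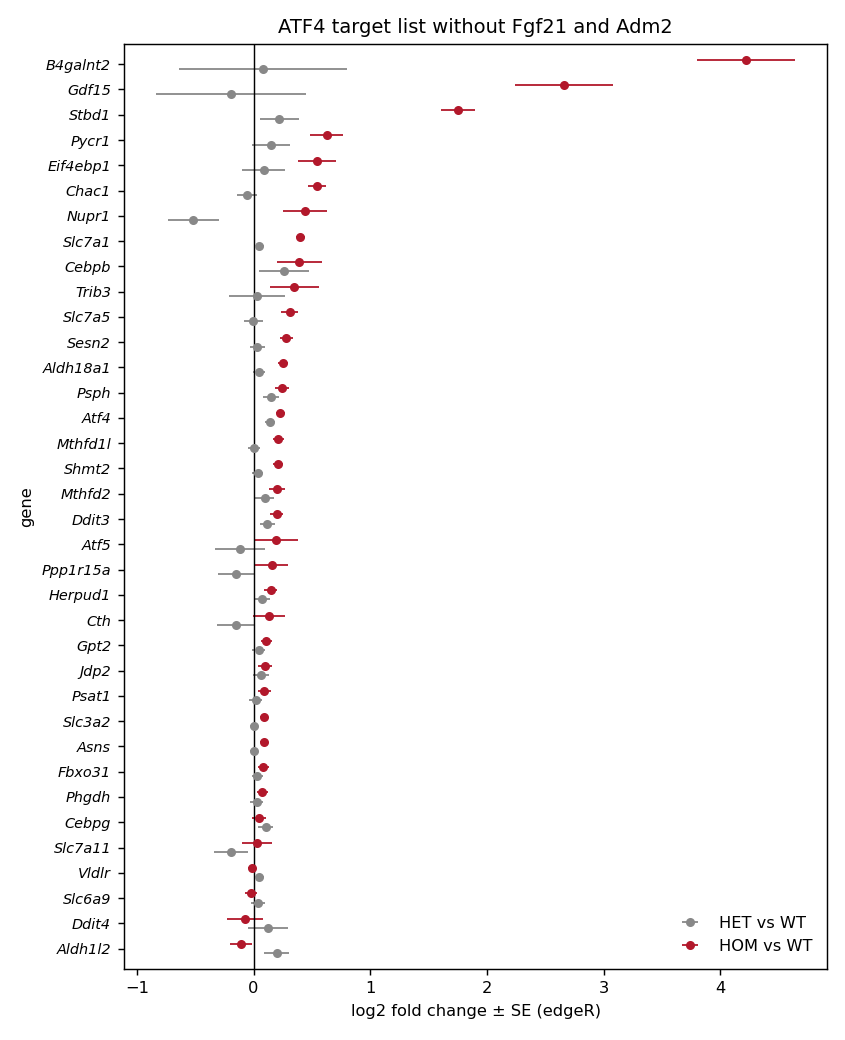
Log2 fold change and SE of each ATF4 target list member in HOM and HET against WT. Fgf21 and Adm2 are left out because WT had 0 and 1 counts.

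Genes of cholesterol synthesis were lower in HOM, 21 of 22, with 5 lower adjusted over the list alone (median -0.10, adjusted p = 5.51e-12, but adjusted p = 0.178 with an estimated correlation), and the median was -0.07 without HOM 3 and -0.06 with the title prefix as a covariate. They included Hmgcs1, which makes the precursor of mevalonate (-0.19, SE 0.0604), and the isomerase Idi1 (-0.26, SE 0.0872). Myelin genes were lower in 19 of 20 (median -0.07, adjusted p = 2.64e-05, but adjusted p = 0.535 with an estimated correlation), with Mbp, a protein of central myelin, at -0.11 (SE 0.0482). The myelin median was -0.04 without HOM 3 (adjusted p = 0.00494), which had the lowest mean level of this list among HOM libraries, and -0.03 with the title prefix (adjusted p = 0.026). All 13 mitochondrially encoded transcripts were lower (median -0.13, adjusted p = 0.000745, but adjusted p = 0.898 with an estimated correlation). This call was lost without WT 5 (adjusted p = 0.171). Cytosolic ribosomal proteins had a median of 0.04 (28 of 35 higher, adjusted p = 0.0227, but adjusted p = 0.925 with an estimated correlation), and the call was lost without HOM 3 (0.224).

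Of 19 cholinergic and motor neuron genes 11 were lower, none passed and 1 passed adjusted over the list alone (median -0.06, adjusted p = 0.0253, but adjusted p = 0.678 with an estimated correlation and 0.0805 without HOM 3). The median was -0.07 with the title prefix as a covariate (adjusted p = 5.87e-05) and -0.03 with the Xist level (adjusted p = 0.00429). Both fits used the preset correlation, so these p-values do not offset the loss of the call with an estimated correlation. The gene that passed over the list was Fgf1, a growth factor of motor neurons, at 276 CPM in WT and 249 in HOM (-0.15, SE 0.0337, adjusted p = 0.109 over all genes). Chat, the enzyme that makes acetylcholine, was at 24.1 and 20.8 CPM (-0.22, SE 0.087, adjusted p = 0.815), with 13.3 CPM in HOM 3. Of 18 genes of axon injury 7 were higher and none passed (median -0.03, adjusted p = 0.209). Of 26 genes linked to inherited neuropathy 13 were higher and none passed (median 0.00, adjusted p = 0.658).

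Astrocyte and microglia lists gave no call in HOM against WT: 12 of 17 astrocyte genes were lower (median -0.01, adjusted p = 0.518), 17 of 23 reactive astrocyte genes higher (0.13, adjusted p = 0.518), 12 of 20 homeostatic microglia genes lower (-0.01, adjusted p = 0.527) and 13 of 21 activated microglia genes higher (0.03, adjusted p = 0.831). None of their members passed. The largest values came from HOM 3: Lcn2, a secreted protein of reactive astrocytes and neutrophils, was at 30.5 CPM there against 2.53 in the next library of the group, and Lyz2, a lysozyme of myeloid cells, at 95.1 against 11.9.

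HOM 3 alone also carried transcripts of peripheral nerve. Prx, which stabilizes peripheral myelin, was at 500 CPM in HOM 3 and at most 1.31 in the other libraries, and Cldn19, a junction protein of Schwann cells, at 72.7 against at most 0.374. Of 16 Schwann cell genes 15 were higher in HOM (median 0.93, adjusted p = 0.0438, but adjusted p = 0.925 with an estimated correlation and 0.884 without HOM 3, when the median was -0.01). The fibroblast list behaved in the same way (median 0.42, adjusted p = 0.0266, but adjusted p = 0.925 with an estimated correlation and 0.884 without HOM 3), with the collagen Col1a1 at 89.3 CPM in HOM 3 and 11.8 in the next HOM library. Endothelial genes had a median of 0.06 (17 of 18 higher, adjusted p = 0.0253, but adjusted p = 0.898 with an estimated correlation and 0.647 without HOM 3). Pericyte and smooth muscle genes had a median of 0.17 (15 of 15 higher, adjusted p = 0.000811, but adjusted p = 0.678 with an estimated correlation and 0.082 with the title prefix as a covariate), and 0.07 without HOM 3 (adjusted p = 0.0316). Blood genes were higher in 11 of 11 (median 0.97, adjusted p = 0.000368, but adjusted p = 0.705 with an estimated correlation), with a median of 0.44 without HOM 3 (adjusted p = 0.00494), and S100a8, of neutrophils, was at 70.8 CPM in HOM 3 against 3.75 in the next HOM library. The Schwann cell, fibroblast and endothelial lists lost their calls with the title prefix too (adjusted p = 0.363, 0.691 and 0.363).

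**Figure D3:**
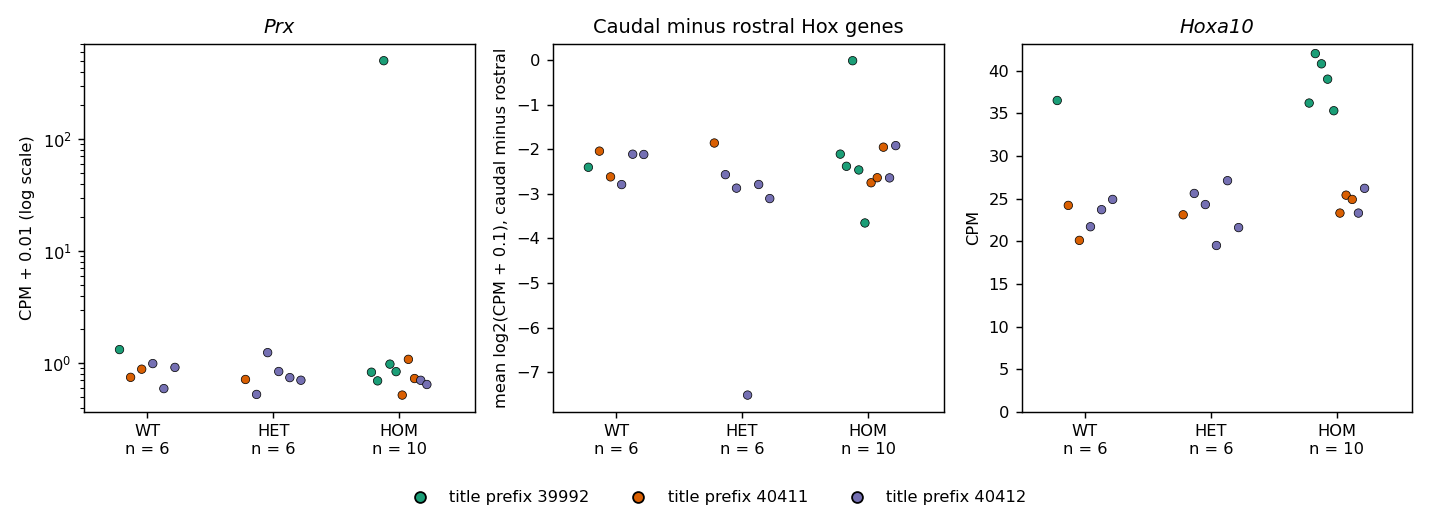
Prx level, mean of caudal minus rostral Hox genes on the log2 scale, and Hoxa10 level in each library. Colors give the prefix of the sample title.

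No gene was called between heterozygous and wild type cords. edgeR called 0 of 16974 genes (smallest adjusted p = 1), and DESeq2, limma voom and limma-trend on TPM each called 0 as well. An unadjusted p below 0.05 was found for 578 genes, fewer than the 849 due by chance. The p-values thus ran high, so the recovery rates in simulated data need not hold for this comparison. Genes changed in HOM stayed near their WT levels: Slc7a1 was at 73.7 CPM (SD 0.992, n = 6), Chac1 at 6.6 (SD 0.524), Cdsn at 0.368 (SD 0.112) and Stbd1 at 1.46 (SD 0.151). Atf4 was at 85.5 CPM (SD 3.86, log2 fold change 0.15, SE 0.0425, adjusted p = 1). Fgf21 had 12 counts in 4 of the 6 HET libraries where WT had 0, at least 4-fold over the floor (adjusted p = 1). The smallest unadjusted p-values belonged to Ppp1r3c, a glycogen targeting protein (0.33, SE 0.0727), Pcdh12, a protocadherin (1.35, SE 0.34), Carmn, a smooth muscle RNA (-1.39, SE 0.361), Aacs, which activates ketone bodies (0.18, SE 0.0504), and Zfp867, a zinc finger protein (-0.26, SE 0.0707), each with an adjusted p of 1.

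As lists, the immediate early genes, switched on within minutes by neuronal activity or stress, were higher in HET in 20 of 20 members, with 5 passing adjusted over the list alone (median 0.36, adjusted p = 1.47e-11, but adjusted p = 0.35 with an estimated correlation). Among them Fos was at 22.1 CPM (SD 8.66) against 12.7 in WT (SD 1.69), and Junb at 14.1 (SD 3.76) against 10.3 (SD 0.805). Cholesterol synthesis genes were higher in 20 of 22 (median 0.06, adjusted p = 6.37e-07, but adjusted p = 0.358 with an estimated correlation), with the demethylase Cyp51 at 133 CPM against 120 (0.15, SE 0.0488). The ATF4 list was higher in 30 of 38 with none passing (median 0.05, adjusted p = 0.0161, but adjusted p = 0.35 with an estimated correlation).

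Heat shock proteins had 14 of 16 members higher in HET (median 0.06, adjusted p = 0.000857, but adjusted p = 0.866 with an estimated correlation), with the chaperone Hspa1a at 21.9 CPM (SD 11.8) against 13.6 (SD 5.91). This median was 0.02 with the title prefix as a covariate (adjusted p = 0.153) and 0.01 with the Xist level as a covariate (adjusted p = 0.799). Axon injury genes were higher in 13 of 18 (median 0.04, adjusted p = 0.0472, but adjusted p = 0.35 with an estimated correlation), and Sox11, a regeneration factor, had 3.11 against 2.46 CPM. Mitochondrially encoded transcripts were lower in 13 of 13 (median -0.07, adjusted p = 0.0291, but adjusted p = 0.964 with an estimated correlation). With the title prefix the axon injury and mitochondrially encoded lists also lost their calls (medians 0.03 and -0.06, adjusted p = 0.153 for each), and the immediate early, cholesterol and ATF4 lists kept theirs (0.28, 0.06 and 0.04). With the Xist level the ATF4 list lost its call (adjusted p = 0.127), and the medians were 0.22 for the immediate early and -0.14 for the mitochondrially encoded genes (adjusted p = 2.32e-05 for each). Leaving out HOM 3, which is not part of this comparison but shares the estimate of spread, moved the number of called lists from 6 to 13.

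Homozygous cords differed from heterozygous cords in 18 genes, 13 higher and 5 lower, with 1493 genes at an unadjusted p below 0.05. The genes with the largest rise over WT rose over HET too: Cdsn 5.82-fold (SE of the log2 value 0.185, adjusted p = 8.41e-09), Stbd1 2.89-fold (SE 0.146, adjusted p = 9.29e-07) and Chac1 1.52-fold (SE 0.0762, adjusted p = 7.03e-05). The ratio for Fgf21 was 53 (30.2 to 103, adjusted p = 8.56e-07). Cyb5r1 rose by 0.36 (SE 0.042, adjusted p = 1.56e-05). Cyp51, of cholesterol synthesis, fell from 133 to 111 CPM (-0.27, SE 0.0434, adjusted p = 0.00355), and Mvd, of the mevalonate pathway, from 21.2 to 17 CPM (-0.33, SE 0.0663, adjusted p = 0.0477). Gramd3, a lipid binding protein, fell by 0.27 (SE 0.0519, adjusted p = 0.0336) and Nol8, a nucleolar protein, by 0.20 (SE 0.0402, adjusted p = 0.0441). Mvd lost its call on leaving out any of 15 of the 22 single libraries (highest adjusted p = 0.127), Nol8 any of 14 (highest 0.127) and Gramd3 any of 10 (highest 0.113), while Cyp51 kept its call in each. The number of calls was 39 without HOM 10, 11 without HOM 1, 11 without HOM 4 and 10 without HET 3. With prefixes 40411 and 40412 alone it was 23, of which 8 were higher, 15 lower and 8 shared with the 18. With the title prefix as a covariate it was 10, and Cyp51 had -0.21 (SE 0.049, adjusted p = 0.329), Mvd -0.19 (SE 0.0589, adjusted p = 0.735), Gramd3 -0.16 (SE 0.0482, adjusted p = 0.757) and Nol8 -0.17 (SE 0.0477, adjusted p = 0.608).

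Cholesterol synthesis genes were lower in HOM than in HET in 22 of 22 members, 2 of which passed over all genes and 18 adjusted over the list alone (median -0.17, adjusted p = 1.91e-29 and 0.00727 with an estimated correlation). Msmo1, a sterol oxidase, was at 118 CPM in HET and 103 in HOM (-0.20, SE 0.0455). The ATF4 list rose, with 33 of 38 higher, 7 passing over all genes, and 17 higher and 1 lower adjusted over the list alone (median 0.19, adjusted p = 2.27e-39 and 2.28e-07 with an estimated correlation). The lower gene was Aldh1l2, a mitochondrial folate enzyme (-0.30, SE 0.093). The tRNA synthetases were higher in 19 of 23, 9 adjusted over the list alone (median 0.04, adjusted p = 1.48e-06, but adjusted p = 0.205 with an estimated correlation). Immediate early genes were lower in 17 of 20 (median -0.28, adjusted p = 2.8e-08, but adjusted p = 0.205 with an estimated correlation), with Egr1 at 52.3 CPM in HET and 34.7 in HOM. Their median was -0.16 with the title prefix as a covariate (adjusted p = 0.000129).

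**Figure D4:**
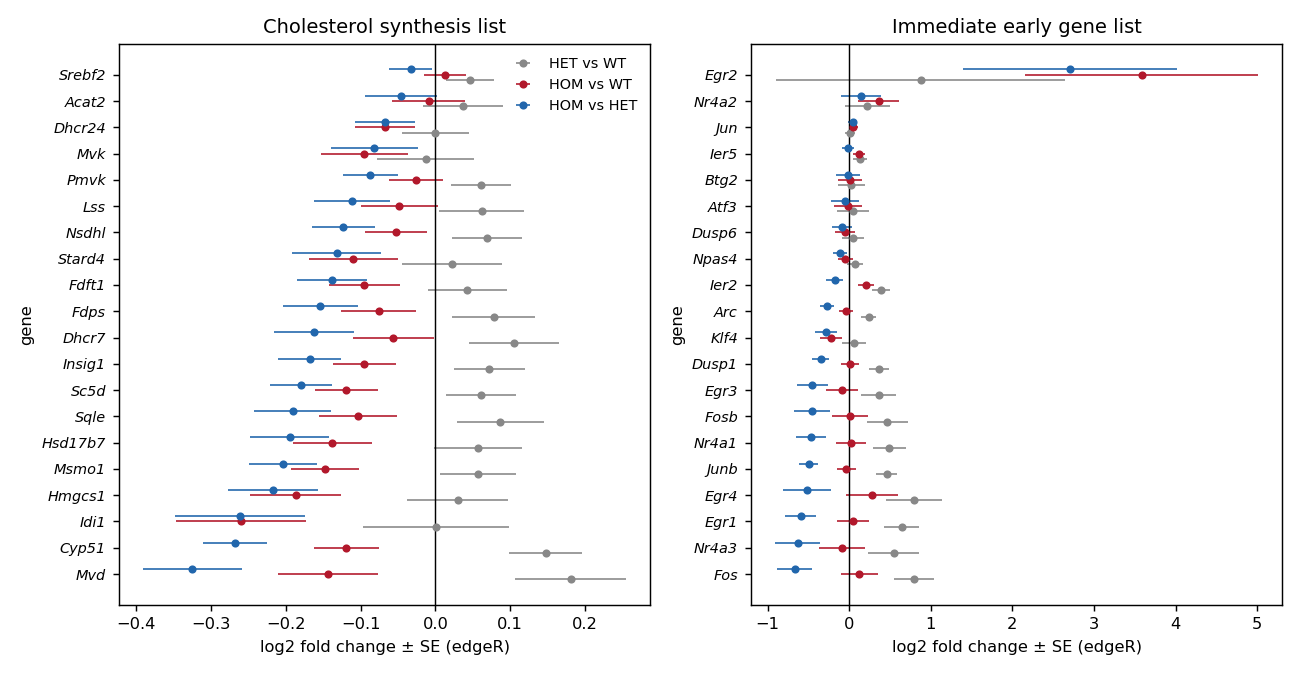
Log2 fold change and SE of cholesterol synthesis genes and immediate early genes in the 3 comparisons, without members not reported here. Egr2 is also a Schwann cell gene and was at 25 CPM in HOM 3.

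Of the neuronal lists, the cholinergic and glutamatergic ones were lower in HOM than in HET without a gene that passed over all genes. Of 20 pan-neuronal synaptic genes 10 were higher (median 0.00, adjusted p = 0.899), and 9 of 16 GABAergic and glycinergic genes were lower (median -0.02, adjusted p = 0.899). The cholinergic and motor neuron genes had a median of -0.11 (11 of 19 lower, 2 of them adjusted over the list alone, adjusted p = 0.00357, but adjusted p = 0.276 with an estimated correlation), with Chodl, a marker of fast motor neurons, at 26.7 and 18.8 CPM (-0.51, SE 0.161). Glutamatergic genes had a median of -0.08 (12 of 16 lower, adjusted p = 0.0144, but adjusted p = 0.0766 with an estimated correlation) and axon injury genes -0.10 (14 of 18 lower, adjusted p = 0.000413, but adjusted p = 0.0581 with an estimated correlation). Heat shock proteins were lower in 16 of 16 (median -0.08, adjusted p = 0.000381, but adjusted p = 0.594 with an estimated correlation). With the title prefix as a covariate the calls of heat shock, axon injury and glutamatergic genes were lost (medians -0.01, -0.05 and -0.04, adjusted p = 0.434, 0.072 and 0.0796), and the cholinergic median was -0.15 (adjusted p = 5.36e-07). The fit with the prefix used the preset correlation only. Myelin genes had a median of -0.10 (adjusted p = 1.21e-06, but adjusted p = 0.205 with an estimated correlation) and oligodendrocyte precursor genes -0.05 (adjusted p = 0.0346, but adjusted p = 0.212 with an estimated correlation), the latter lost without HOM 3 (0.0552).

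Vascular, interferon, complement, blood and nerve lists were higher in HOM than in HET, with HOM 3 as the largest value in several. Microglia lists were not called (medians -0.03 for homeostatic and -0.01 for activated genes, adjusted p = 0.294 for each), and the activated list was called lower without HOM 3 (-0.04, adjusted p = 0.0124) or with the Xist level (-0.03, adjusted p = 0.0303). Interferon response genes had a median of 0.25 (19 of 22 higher, adjusted p = 0.000157, but adjusted p = 0.592 with an estimated correlation), with Ifit3 at 11.4 CPM in HET and 14.7 in HOM. Complement and antigen presentation genes had a median of 0.24 (adjusted p = 0.00416, but adjusted p = 0.594 with an estimated correlation), and Cd74, which guides antigen loading, was at 54.9 CPM in HOM 3 and 2.87 in the next HOM library. Endothelial genes had a median of 0.06 (adjusted p = 0.0127, but adjusted p = 0.594 with an estimated correlation and 0.357 without HOM 3), pericyte genes 0.16 (adjusted p = 0.00114, but adjusted p = 0.499 with an estimated correlation) and fibroblast genes 0.56 (adjusted p = 0.00023, but adjusted p = 0.594 with an estimated correlation). Without HOM 3 the medians were 0.08 for interferon, 0.05 for complement, 0.04 for pericyte and 0.12 for fibroblast genes (adjusted p = 0.0139, 0.0231, 0.0108 and 0.00227). These p-values used the preset correlation. With an estimated correlation none of these lists was called even with HOM 3 included. With the title prefix the endothelial, pericyte, fibroblast and Schwann cell lists lost their calls (adjusted p = 0.468, 0.192, 0.195 and 0.492), and with the Xist level the complement, endothelial and Schwann cell lists did (0.0847, 0.107 and 0.197). Schwann cell genes had a median of 0.83 (adjusted p = 0.0418, but adjusted p = 0.9 with an estimated correlation and 0.681 without HOM 3) and blood genes 1.14 (adjusted p = 0.0112, but adjusted p = 0.641 with an estimated correlation and 0.187 without HOM 3).

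Across 0, 1 and 2 mutant alleles 17 genes changed, 16 up and 1 down, with 1171 at an unadjusted p below 0.05. They were the 16 genes of HOM against WT and Shmt2, which feeds one-carbon units from serine (log2 change per allele 0.11, SE 0.0216, adjusted p = 0.0332). Per allele, Slc7a1 rose by 0.21 (SE 0.0244, adjusted p = 1.31e-05), Atf4 by 0.11 (SE 0.0188, adjusted p = 0.00415) and Cars by 0.10 (SE 0.0151, adjusted p = 0.0013), and Mrvi1 fell by 0.24 (SE 0.0459, adjusted p = 0.0227). The Mrvi1 call was lost without WT 1 or 3 or HOM 1, 2, 6, 7, 9 or 10, and with the title prefix as a covariate. For Slc7a1, Chac1, Cdsn and Stbd1 the HET means given above lay near WT rather than midway. For Atf4 the HET mean of 85.5 CPM lay past the midpoint between 77.3 in WT and 90.6 in HOM.

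The log2 fold changes of HOM and HET against WT correlated across 16974 genes with r = 0.296 and covariance 0.0116. Because the WT libraries are shared, simulated unchanged groups gave a higher mean r of 0.56 (SD 0.0356, 20 simulations) and covariance of 0.0194. The simulated groups carried no effect of the title prefix and were fitted without it as a covariate. The observed r with the prefix as a covariate, given below, therefore has no matching simulated value. Whether the prefix accounts for the lower observed r was not tested. With the WT libraries split so that the comparisons shared none, the mean r from mean log2 CPM was 0.014 (-0.035 to 0.051), against 0.448 by the same measure with all 6 WT libraries shared. Near Yars on chromosome 4, within 20 Mb, 1 of 491 tested genes was called in HOM against WT, namely Sesn2, and 15 of 16483 elsewhere (odds ratio 2.24, 0.0531 to 14.6, p = 0.375).

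The title prefix, whose meaning the labels do not give, went with 328 genes in a model with genotype. Hoxc10, a Hox gene of the lumbar cord, was at 50.8 to 58.2 CPM in prefix 39992 and 27.6 to 38 in the others (adjusted p = 1.06e-05), and Hoxa10 at 35.3 to 42 and 19.5 to 27.1 (adjusted p = 2.17e-05). WT 1, the only WT library of that prefix, had 36.5 CPM of Hoxa10, within the range of the 5 HOM libraries. Hoxd9 was called too (adjusted p = 0.00388), but Hoxd10 was not (adjusted p = 0.276), at 20.3 to 47.8 CPM in prefix 39992 and 1.9 to 22.8 in the others. Caudal Hox means (log2) overlapped: 0.67 to 2.03 in prefix 39992 without HOM 3, and 1.22 to 2.25 in the others without HET 4. Prefix 39992 held 1 WT, 0 HET and 5 HOM libraries, so comparisons with HET cannot be made within it.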

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

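Group values were compared with the other libraries of their group by the Dixon ratio for library totals, 137 genes and 24 lists, 485 group values in all, and 75 stood apart. By chance such a ratio marks about 1 in 20 groups, so a number of these are due to chance. In this part the Hox gene groups, the tests on HOM 3 and the tests of Fgf21 reads were chosen only after the result was seen. All predictions behind the tests below were likewise written down after values had been seen.

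HOM 3 stood apart in most of them. Peripheral nerve genes were high: Prx 500 CPM, Plekha4 96 and Cldn19 72.7. Fibroblast genes were high as well: Dcn 161, Ogn 108, Col1a1 89.3, Bgn 29, Fbln5 23.1, Mgp 20 and Aldh1a2 9.15. So were vascular and smooth muscle genes: Cdh5 27.8, Tagln 24.3, Myl9 22.6, Myh11 19.9, Acta2 16.7 and Mustn1 2.04. Blood and immune genes followed: S100a9 96.6, Lyz2 95.1, Ngp 89.8, S100a8 70.8, Ltf 58.8, Cd74 54.9, Slc4a1 51.9, Serping1 37.7, Lcn2 30.5, H2-Eb1 23, Cybb 13.7 and Psmb9 4.26. Osmr, of the reactive astrocyte list, was high at 11, and Nupr1, of the ATF4 list, at 4.5. Mrvi1 was high at 11 CPM. Genes of the cord's own cells were low in HOM 3: Mbp 8680 CPM, Trf 983, Stmn4 88.2, Csf1 40.5, Enpp6 14.9 and Chat 13.3.

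The list means of HOM 3, as mean log2 CPM, were high for blood (7.02), Schwann cells (6.31), endothelial cells (5.40), activated microglia (4.93), complement and antigen presentation (4.79), fibroblasts (4.75), reactive astrocytes (4.55) and pericytes (3.41). They were low for oligodendrocytes (8.31), homeostatic microglia (4.22) and glutamatergic neurons (3.86).

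In HOM 3, 10 of the 16 Schwann cell genes were at least 4-fold above the median of the other 21 libraries. That count restates the observation, so nerve or root tissue in the dissected piece stays open and untested. The caudal minus rostral Hox value of HOM 3 lay 1.85 above the highest other library, so its piece may have been more caudal. That value does not test whether a caudal piece brings nerve transcripts, so this account stays open too. The homozygous genotype is a poor account, since only 1 other HOM library had a Schwann cell mean above the highest WT or HET library. The piece and the nerve tissue are not exclusive accounts, and nothing here separates them. Peripheral nerve transcripts in HOM 3 are unlikely to explain the HOM genes, 15 of 16 of which stayed called without this library.

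Other libraries stood apart in fewer values, and at the chance rate given above many of these may be due to chance. In WT 5, mt-Nd6 was high at 1150 CPM, Aqp4 at 736, Ermn at 397 and Gap43 at 97.9, and Rps2 was low at 150. In WT 1, Chat was high at 29.2, Aldh1a2 at 3.14 and Adm2 at 0.0305, the last from 1 count. WT 2 had the largest total, 42.8 M counts. Aldh18a1 was high in WT 4 at 28.6, Hspa1a in WT 6 at 25.1, and Col1a1 low in WT 6 at 6.51 and Psph low in WT 3 at 10.1. In HET 2, Acta2 was high at 7.9, S100a9 at 1.89, S100a8 at 1.2 and Mustn1 at 0.83. Sox10 was low in HET 3 at 106, Ly6a in HET 1 at 9.88 and Oasl2 in HET 6 at 4.61. In HOM 10, Dnajb1 was high at 71.8, Ppp1r3c at 69.4, Egr1 at 59.7, Hspa1a at 38.5 and Fos at 23.7. In HOM 8, Bsg was high at 400, and Calca was high in HOM 9 at 21.2.

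The 16 genes of HOM against WT were weighed against properties of the libraries. All 16 stayed called with the Xist level as a covariate, so the sex of the animals is an unlikely cause. With the title prefix as a covariate 13 stayed called, so the prefix is an unlikely cause of those. Acsl5, Aldh18a1 and Wars lost their calls (adjusted p = 0.0542, 0.0815 and 0.112) with log2 fold changes of 0.16 (SE 0.0316), 0.24 (SE 0.0497) and 0.15 (SE 0.0335), against 0.17 (SE 0.0294), 0.25 (SE 0.0454) and 0.17 (SE 0.0316) without it. Their calls ended because the SE rose and the fold changes shrank slightly. With prefixes 40411 and 40412 alone, a fit with fewer libraries, 8 of the 16 stayed called. Among the 13, Atf4, Cars and Sesn2 lost their calls there (adjusted p = 0.301, 0.271 and 0.115). Their log2 fold changes were 0.221, 0.185 and 0.337, against 0.23, 0.194 and 0.281 with all libraries. All 16 genes kept their direction within each prefix, but they were chosen in these same libraries, so this adds no evidence against the prefix. Among 100 splits of the same libraries that included the real one, 1 split, the real one, gave as many genes for HOM against WT, 1 of 100 for HOM against HET and 1 of 100 for the allele trend, so chance is an unlikely cause. The splits did not balance the title prefix, so they cannot weigh it. With the prefix as a covariate, HOM against HET had 10 calls, of which 8 were shared with the 18 without it. For HET against WT the real split gave 0 genes, which all 100 of 100 splits reach by construction, so nothing is tested there. Of those splits 1 gave 602 genes, which points to a structure of the libraries other than genotype, with mitochondrial shares of 4.84% to 6.28% on one side and 6.25% to 7.79% on the other.

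Fgf21 reads in HET libraries were few, 12 in all. WT libraries had none, and an exact binomial test of equal rates in WT and HET gave p = 0.000164. That test treats the reads as independent and was prompted by the same reads, and the labels do not give the lanes, so misassignment of reads from HOM libraries stays open. An exact permutation of HET against WT levels gave p = 0.0606, the lowest that reads in 4 of the 12 libraries allow, so it decides nothing about chance spread between libraries. A low induction of Fgf21 in heterozygotes is open as well.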

How the results depend on the processing

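In this part the fits without HOM 3 and HET 4 and with the Gm42418 level as a covariate were chosen only after the result was seen. RLE scaling changed the direction or call of none of 224 gene and list results, and moved the genes of HOM against HET from 18 to 19. Counts within a factor of 1.5 of the reported one were taken as the same. Where no cause is given, the cause was not tested.

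For HOM against WT the number of genes, 16, became 8 with prefixes 40411 and 40412 alone, all 8 shared, and 28 with DESeq2, with all 16 shared. It ran from 12 to 19 when leaving out single libraries. Cdsn, Fgf21, Stbd1, Slc7a1, Adm2, Cyb5r1 and Chac1 were called in every setting that kept them among the tested genes. The number of lists, 12, became 6 with prefixes 40411 and 40412 alone and 1, the ATF4 list, with an estimated correlation (8 to 14 leaving out single libraries).

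For HET against WT the number of genes was 0 in every setting. The number of lists, 6, became 3 with the title prefix as a covariate, 11 with prefixes 40411 and 40412 alone, 0 with an estimated correlation, 10 without HOM 3 and HET 4, 10 with the Gm42418 level and 12 with only the groups compared. It ran from 4 to 13 when leaving out single libraries, so these lists rest on the settings.

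For HOM against HET the number of genes, 18, became 11 with limma-trend on TPM, 10 with the title prefix, 29 with the Gm42418 level (14 higher, 15 lower) and 72 with DESeq2 (35 higher, 37 lower), and ran from 10 to 39 when leaving out single libraries. With prefixes 40411 and 40412 alone it was 23, with 8 higher and 15 lower against 13 and 5, and 8 shared. The number of lists, 17, became 2 with an estimated correlation, ATF4 targets and cholesterol synthesis (15 to 18 leaving out single libraries). The allele trend, 17 genes, became 5 with prefixes 40411 and 40412 alone and 32 with DESeq2 (12 to 23). The fold change correlation, 0.296, became 0.072 with genes of at least 5 CPM, 0.518 with the title prefix and 0.382 with the CPM filter. Unchanged groups were not simulated under these settings, so these values cannot be set against the simulated mean r of 0.56.

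Values that changed sign were mostly genes that HOM 3 carries. In HOM against WT, without HOM 3 and HET 4, Cybb was -0.013, Ogn -0.167, Dcn -0.093 and Prx -0.214, the fibroblast list 0.003 with the test pointing down and the Schwann cell list -0.020. With DESeq2, Cybb was -0.025, Ogn -0.179, Dcn -0.092 and Prx -0.214. These lie near the values without HOM 3, so DESeq2 is not taken as a separate check on them. With prefixes 40411 and 40412 alone, Ogn was -0.104, Dcn -0.080, Aldh1a2 -0.074, Prx -0.155 and the Schwann cell list 0.009 with the test pointing down. Leaving out single libraries, Cybb ran from -0.011 to 1.472, Ogn from -0.165 to 3.191, Dcn from -0.091 to 1.304, Prx from -0.213 to 5.973, the fibroblast list from 0.003 to 0.516 and the Schwann cell list from -0.013 to 1.005, each lowest without HOM 3.

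In HOM against HET, Prx was -0.098 with prefixes 40411 and 40412 alone, -0.020 with DESeq2 and -0.021 to 6.180 leaving out single libraries, and S100a8 was -0.414 with those prefixes alone. The Schwann cell list was 0.027 without HOM 3 and HET 4, with the test pointing down, and -0.011 to 0.915 leaving out single libraries. With the title prefix as a covariate Hspa1a was 0.007 and Adcyap1 0.014. Yars in HET against WT ran from -0.005 to 0.027 leaving out single libraries.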

Other observations

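The libraries differed in their Hox gene levels. In HET 4 Hoxa11 and Hoxd11 had 1 count each and Hoxc11, Hoxc12 and Hoxc13 had 0. The 20 libraries other than HOM 3 had 1.96 to 6.08 CPM of Hoxa11, 7.63 to 16.6 of Hoxd11, 4.29 to 8.58 of Hoxc11, 1.4 to 5.83 of Hoxc12 and 0.415 to 3.2 of Hoxc13. Hoxb13 also had 0 in HET 4, within their 0 to 1.76 CPM. In HET 4 Hoxd10 was at 1.9 CPM against 9.95 to 28.6, and the rostral gene Hoxb5 was at 41.9 CPM, within 32.1 to 42. HOM 3 was the opposite, with Hoxd11 at 35.5 CPM, Hoxc11 at 20.5 and Hoxc12 at 12.6.

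Xist was below 1 CPM in 1 of 6 WT, 4 of 6 HET and 4 of 10 HOM libraries, and at least 416 CPM in the rest, so the groups differed in their likely share of males, while all 16 genes of HOM against WT stayed called with the Xist level as a covariate. The labels give no sex.

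Gm42418, an annotated gene at a ribosomal RNA locus, ranged from 6260 to 57800 CPM between libraries, and Lars2, annotated as a mitochondrial leucyl-tRNA synthetase, from 187 to 2710 CPM. Group means of Lars2 were 1100 CPM in WT (SD 1040), 429 in HET and 974 in HOM (SD 661), and of Gm42418 26700 (SD 21000), 12700 (SD 5150) and 24200 (SD 14000). Both were highest in WT 4 (Gm42418 57800 and Lars2 2710 CPM) and lowest in WT 5 (6260 and 187 CPM). The group means of Lars2 therefore cannot be read apart from those of Gm42418. Lars2 is a member of the mitochondrial synthetase list.

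The mean level of the ATF4 list without Fgf21 was 0.0279 higher in HET than in WT on the log2 scale (exact permutation p = 0.165), and 0.422 higher in HOM.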
